A study of Mus musculus with 6 samples.

How the data were processed

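Total RNA from cleared mammary fat pads, which the labels call mammary stroma, was measured on 6 arrays, 3 from Rarb -/- mice and 3 from their wild-type littermates, at 4 weeks of age. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled cRNA was prepared from it by an Affymetrix protocol. A description attached to every sample also ties ErbB2 to the mice, which it calls young, without saying whether they carried a transgene. Since it is the same for both genotypes it defined no group, but what wild type and Rarb-null mean beyond Rarb is uncertain for that reason. Neither the array design, nor the number of mice behind each array, nor the build of the probe annotation is given in the sources used here.

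The deposited value table holds 1 value on the log2 scale per probe set and array, made by the authors with RMA per the submitters' processing notes, which give no version. RMA subtracts background, forces the arrays to a common distribution of probe signals, and summarises the probes of each set, so a shift shared by most transcripts would be removed and small differences of dim or very bright probe sets are compressed. The deposited log2 values ran from 3.25 to 15.3, and the array medians lay between 6.78 and 6.85. The file carries no detection flags, so no probe set could be called present or absent, and the number of arrays, not a read depth, limits the precision. A second deposited table holds the authors' group means and fold change on the log2 scale. The authors made a score, the SAM d-score, and a p-value for each probe set by comparing the 2 groups with SAM, per the file headers. How SAM was run, and how the p-value was made, is not given in the sources used here. The authors' log2 fold changes equalled the differences of the group means of the value table within 7.4e-06, with Rarb-null minus wild type as their direction. No pair of arrays held the same values: the closest pair still differed by up to 4.14 log2 units at a probe set.

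The value table lists 45101 probe sets. The 64 control probe sets were left out, and 45037 were tested. Gene symbols were taken from the authors' deposited table. Of the tested probe sets, 40149 named 1 gene symbol, 1239 named several and 3649 named none. Old symbols were updated through a table of RefSeq genes on the assembly GRCm38.p6: 28011 of the single-symbol probe sets carried a current symbol, 8412 were updated through a synonym that belongs to 1 gene, and 3726 had no match and kept the deposited symbol. They name 20519 genes. Since no build is named for the arrays, no coordinate of that assembly is printed, and it served only for names and for which genes neighbour Rarb.

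Rarb-null and wild-type arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values, without covariates, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Standard errors and 95% intervals come from the moderated variance. For results per gene, the probe set with the highest mean over the 6 arrays was taken among those that name 1 gene. There were 36 gene lists, 20 of pathways or functions and 16 of cell type markers, 597 genes in all, of which 572 had such a probe set. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 36 lists, with camera at an estimated correlation and fry, which asks whether a list's genes move one way without reference to other genes, beside it. An exact permutation test over the 10 splits of the 6 arrays, which cannot give a p under 0.1, was applied to the mean of each list and to the correlations between arrays. Genes within 10 Mb of Rarb were compared with all other placed genes by Fisher's exact test, since DNA around a targeted gene can come from another strain. The procedure was tested on simulated data with the means and spreads of these probe sets and independent noise: among 200 changed probe sets of 45037, it recovered 46% of those changed 2-fold and 77% of those changed 4-fold, in the right direction, and called 7 unchanged probe sets. Real probe sets vary together, so these shares are a guide to the noise of single probe sets only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

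Before the data were examined, the design, the lists, the alternatives and the rule for named genes were fixed. The rule took Rarb; in each direction up to 12 genes past the threshold with no overlap between groups or, with fewer than 8, the 8 with the smallest p among genes changed at least 1.5-fold with no overlap, leaving out clone and model names; for each list the members past 0.05 adjusted over the list alone (at most 4) or else the 2 with the smallest p; and Cxcl12 and Pparg. Results of 3 genes that the rule named are not reported here. The alternatives were a further quantile normalization, median centring, removal of dim probe sets (the lowest 40% by mean signal, or a mean under 6), a trended robust prior, array weights, the replicate number as a block, removal of probe sets whose names end in _x_at or _s_at, other thresholds, other ways to summarise a gene, other list tests, other windows around Rarb, and each array left out in turn. After the absence of calls had been seen, the first principal component and the level of the spiked hybridisation controls were added as covariates. The labels give both groups replicate numbers 1 to 3 but do not say that a number marks a litter or a day.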

Results

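The series asked which genes of the mouse mammary stroma are expressed differently when retinoic acid receptor beta, a nuclear receptor encoded by Rarb, is missing. Genome-wide expression was measured in cleared mammary fat pads, the fatty connective tissue bed of the gland, of 4-week-old Rarb -/- mice (3 arrays, called Rarb-null) and their wild-type littermates (3 arrays). Expression is the deposited log2 RMA value of a probe set, and 1 log2 unit is a 2-fold difference in signal. Whether each array came from 1 mouse or from pooled tissue is not given in the sources used here, so p-values measure the spread between these arrays. Group values are means ± SD over 3 arrays, and differences are Rarb-null minus wild type.

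Rarb signal was not lower on the arrays labelled Rarb-null. Its single probe set read 6.50, 6.61 and 7.41 on Rarb-null replicates 1 to 3 and 6.95, 6.01 and 6.65 on wild-type replicates 1 to 3. The means were 6.84 ± 0.49 and 6.54 ± 0.48 (SD, n = 3 each), a difference of 0.30 log2 with a 95% interval from -0.43 to 1.03. The adjusted p in limma was 0.951, and the groups overlapped. The highest of the 6 values belonged to Rarb-null replicate 3 and the lowest to wild-type replicate 2. Whether this probe set lies in the deleted part of the gene is not given in the sources used here. It therefore checks nothing about the labels, and Rarb-null below means labelled as such.

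**Figure D1:**
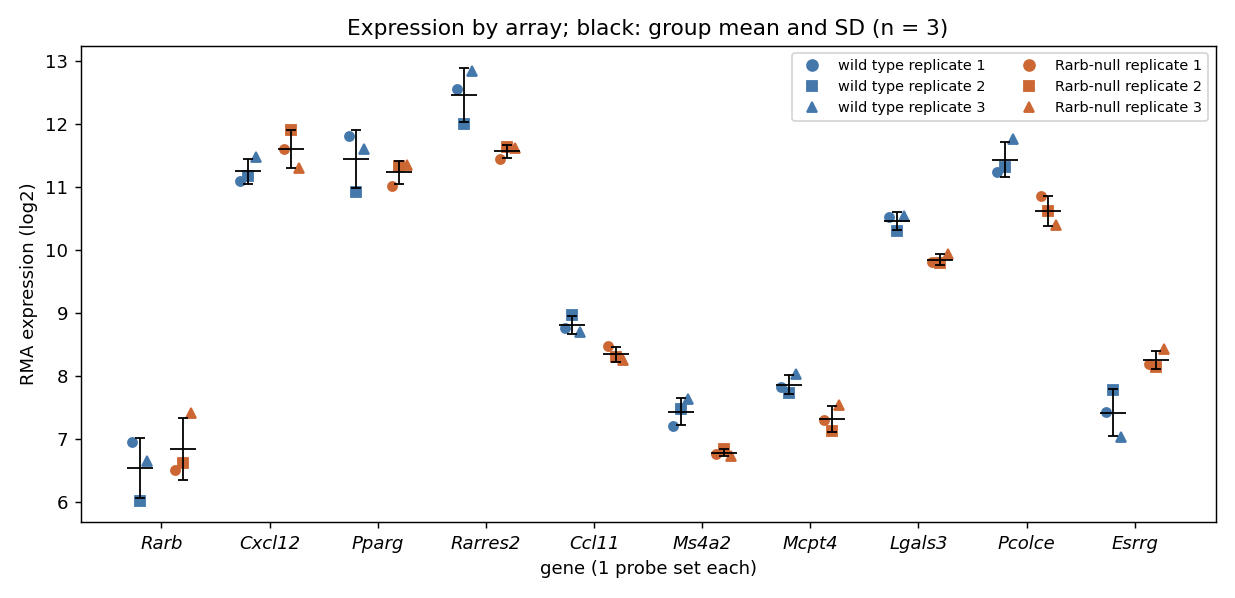
Expression (y axis, log2 RMA signal) of Rarb and 9 further named genes (x axis, 1 probe set each) on every array; colours mark wild type and Rarb-null, symbols the replicate, and black bars the group mean and SD over 3 arrays. The groups overlap for Rarb, Cxcl12 and Pparg and are apart for the other 7 genes, none of which passed the threshold over all probe sets.

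No gene passed the threshold between Rarb-null and wild-type stroma. Of 45037 probe sets, 0 passed an adjusted p of 0.05 in limma and 0 passed 0.10, and the smallest adjusted p was 0.908. At an unadjusted p under 0.05 there were 2351 probe sets, 1052 higher and 1299 lower on Rarb-null arrays, where chance gives 2252. At an unadjusted p under 0.01 there were 358, where chance gives 450. The 2 groups did not overlap at 4705 probe sets, 10.4% of all, and chance gives 10%. In 970 probe sets the means differed at least 1.5-fold, and in 333 of them the groups did not overlap either. Probe sets picked for a large difference of means overlap less often for that reason alone. The 10% is therefore no measure for the 333. The median standard error of a difference was 0.14 log2, and for 93.2% of probe sets the 95% interval excluded a 2-fold difference either way. This share counts dim probe sets, whose differences RMA compresses, and the intervals are not adjusted for the number of probe sets. It is therefore no evidence of absence for genes with little signal. In the authors' deposited table, 2452 probe sets had a p-value under 0.05 and 349 under 0.01, and its smallest p-value was 0.0011. Centring each array on its median left 816 higher and 1692 lower among 2508 probe sets at an unadjusted p under 0.05. Without Rarb-null replicate 2 the count past 0.05 adjusted was 1, a probe set with 2 provisional gene symbols in the authors' deposited table that also occur on a probe set of the immunoglobulin lambda gene Igl-V1, where the difference was 2.92 log2 and the adjusted p in limma 0.0339. The count at an unadjusted p under 0.05 was 1147 without Rarb-null replicate 2, 4418 without wild-type replicate 2 and 1307 without wild-type replicate 3.

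**Figure D2:**
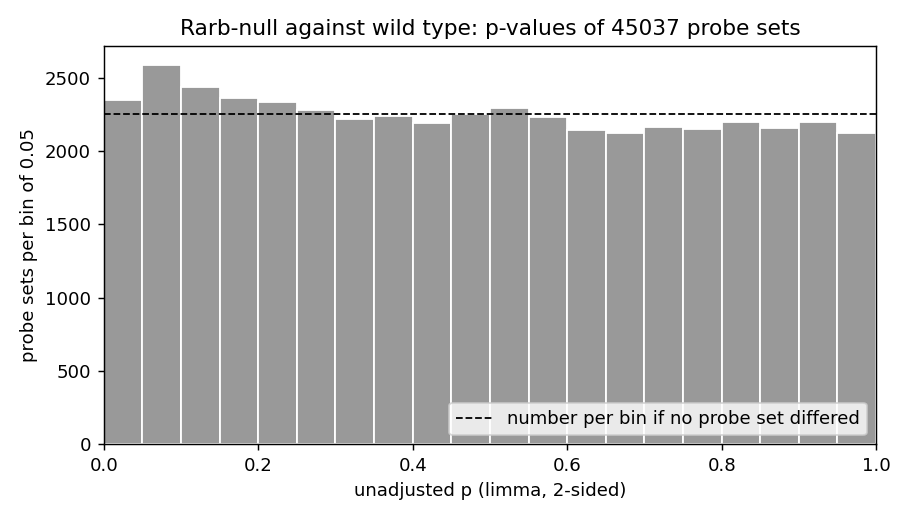
Number of probe sets (y axis) per bin of 0.05 of the unadjusted limma p (x axis) for Rarb-null against wild type; the dashed line is the number per bin if no probe set differed. The lowest bin holds 2351 probe sets, close to the 2252 that chance gives.

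None of the following genes passed the threshold, and each is given by its values as the leading non-overlapping difference of at least 1.5-fold. Among genes with higher signal on Rarb-null arrays, Phxr4 read 10.02 ± 0.16 against 9.04 ± 0.29, which is 1.97-fold. Auts2 read 8.62 ± 0.06 against 7.56 ± 0.55, or 2.10-fold, and 12 of its 15 other probe sets had the same sign. Acsm3, an acyl-CoA synthetase of medium-chain fatty acids, read 8.54 ± 0.40 against 7.62 ± 0.09. The orphan nuclear receptor gene Esrrg read 8.25 ± 0.15 against 7.41 ± 0.37, with both of its other probe sets of the same sign. Mapk8, which encodes a Jun N-terminal kinase, read 9.47 ± 0.16 against 8.77 ± 0.21, and 3 of its 4 other probe sets had the same sign. Tmem64, Rufy3 and Oip5os1 differed by 1.61-fold, 1.59-fold and 1.56-fold. Of the 5 other probe sets of Rufy3, 1 had the same sign, as had 1 of the 2 of Oip5os1. Among genes with lower signal, Lgals3, the galectin-3 gene, read 9.84 ± 0.08 against 10.46 ± 0.14, 1.53-fold lower. Pcolce, whose product enhances the processing of procollagens, read 10.62 ± 0.23 against 11.43 ± 0.28, 1.76-fold lower. Tmprss2, a membrane serine protease gene, was 1.72-fold lower with all 3 other probe sets of the same sign. Lztr1 was 1.71-fold lower, but its other probe set had the opposite sign. Nkapl read 5.63 ± 0.07 against 6.33 ± 0.26, Znrd1as 7.32 ± 0.07 against 7.91 ± 0.16, and Pfdn1, a prefoldin chaperone subunit gene, 8.31 ± 0.14 against 8.90 ± 0.07. Ms4a2, a chain of the high-affinity IgE receptor of mast cells, read 6.77 ± 0.06 against 7.43 ± 0.22, 1.58-fold lower, and its other probe set had the opposite sign. Adjusted p was 0.908 for all 16 of these genes.

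Retinoid pathway genes showed small differences, mostly toward lower signal on Rarb-null arrays. Of 10 measured genes for retinoid receptors and their partners, 8 had a lower mean on Rarb-null arrays, with a median difference of -0.19 log2, and camera placed this list past the threshold (adjusted p = 0.035 with the preset correlation). That call did not hold with an estimated correlation, where the unadjusted p was 0.103. The list's mean was lower on every Rarb-null array than on any wild-type array, which gives an exact permutation p of 0.1, the smallest possible here and one that 3 of the 36 lists reached, where chance gives 10%. The call held without Rarb-null replicate 2 (adjusted p = 0.00497) or wild-type replicate 1 (0.0275) and was lost without any other array, with an adjusted p of 0.221 at most, without Rarb-null replicate 3. No member passed, over all genes or adjusted over the list alone. Rxrb, a retinoid X receptor gene, read 10.01 ± 0.09 against 10.28 ± 0.10. Of 20 genes of retinoid metabolism and binding, 14 had a lower mean (camera adjusted p = 0.257). Its leading members by p were Adh1, an alcohol dehydrogenase that can oxidise retinol, at 11.63 ± 0.15 against 12.20 ± 0.33, and the retinaldehyde dehydrogenase gene Aldh1a1 at 10.43 ± 0.20 against 11.04 ± 0.42. The other probe set of Aldh1a1 had the opposite sign. Of 23 retinoic acid response genes, 15 had a lower mean (camera adjusted p = 0.257). Rarres2, which encodes the adipokine chemerin, read 11.57 ± 0.10 against 12.46 ± 0.43, a 1.86-fold difference, and both other probe sets had the same sign. Tgm2, a transglutaminase gene, read 12.63 ± 0.25 against 13.11 ± 0.25. The response list passed without wild-type replicate 2 (adjusted p = 0.0358). Members of these 2 lists overlap, with 6 genes of each held by another list, and 0 members passed.

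Chemokine, matrix and signalling genes did not pass as lists, and 0 of their members passed. With the mean of all probe sets of a gene in place of the brightest, the chemokine list passed (camera adjusted p = 0.0112), as did basement membrane genes (0.0342), both as lower. Cxcl12, a chemokine of stromal fibroblasts, read 11.60 ± 0.30 on Rarb-null and 11.25 ± 0.20 on wild-type arrays, a difference of 0.35 log2 with a 95% interval from -0.07 to 0.78 and an adjusted p of 0.908, and 1 of its 2 other probe sets had the same sign. In the chemokine list, 11 of 16 genes had a lower mean (camera adjusted p = 0.165), led by Ccl11, the eotaxin gene, at 8.34 ± 0.12 against 8.81 ± 0.15, and Ccl7 at 5.50 ± 0.05 against 5.79 ± 0.14. Fibrillar and structural matrix genes were split, 11 higher and 9 lower (camera adjusted p = 0.766), with fibronectin Fn1 at 13.31 ± 0.27 against 12.68 ± 0.72 and Sparc differing by -0.28 log2. Among basement membrane genes 10 of 13 had a lower mean (camera adjusted p = 0.132), with the laminin gene Lamb2 at 9.31 ± 0.17 against 9.71 ± 0.13 and the collagen gene Col15a1 differing by -0.45 log2; this list passed without Rarb-null replicate 2 (adjusted p = 0.0108). Of matrix proteases and inhibitors (camera adjusted p = 0.968), Timp4, a metalloproteinase inhibitor gene, read 10.25 ± 0.21 against 11.98 ± 1.32, with the wild-type arrays far apart, and the aggrecanase gene Adamts5 differed by -0.74 log2. Wnt signalling genes gave a camera adjusted p of 0.960; Sfrp5, a secreted Wnt antagonist gene, read 6.96 ± 0.21 against 7.97 ± 0.68, and Dkk2, another antagonist gene, differed by -0.51 log2. TGF-beta and BMP signalling genes (camera adjusted p = 0.892) were led by Tgfbi at -0.36 log2 and Id3 at -0.27 log2. Growth factors and their receptors (0.835) were led by Angpt1 at 0.60 log2 and Fgf1 at -0.33 log2. Hormone receptors (0.788) were led by the oestrogen receptor gene Esr1 at 0.30 log2 and the thyroid hormone receptor gene Thra at -0.18 log2. Among immediate early and stress genes (0.766), Fosb differed by 0.71 log2 and Egr1 by -0.49 log2. Of the circadian clock genes (0.204), Clock differed by -0.19 log2 and Cry2 by 0.29 log2, and the list passed without wild-type replicate 1 (adjusted p = 0.00171). Interferon response genes had 15 of 17 lower means (camera adjusted p = 0.136), with Gbp2 at 10.89 ± 0.07 against 11.42 ± 0.35 and the immunoproteasome gene Psmb9 at -0.46 log2, and the list passed without Rarb-null replicate 1 (adjusted p = 0.0203) or 2 (0.00819). Median, mean and camera direction differed in sign for 6 of the 36 lists: matrix proteases (median 0.07, mean -0.14, camera down), Wnt signalling (0.01, -0.02, up), macrophages (0.03, -0.0013, up), T and NK lymphocytes (-0.03, -0.01, up), neutrophils (0.01, -0.03, down) and salivary gland (-0.02, 0.08, up).

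Genes of adipocytes, the main cells of a fat pad, did not pass either. Pparg, the nuclear receptor that drives fat cell differentiation, read 11.23 ± 0.19 on Rarb-null and 11.44 ± 0.46 on wild-type arrays, a difference of -0.21 log2 with a 95% interval from -0.76 to 0.34 and an adjusted p of 0.957. Of 24 genes of adipocyte differentiation and lipid storage, 17 had a lower mean (camera adjusted p = 0.132), and the differentiation factors Cebpd and Cebpa read 9.58 ± 0.50 against 10.25 ± 0.04 and 11.43 ± 0.37 against 12.06 ± 0.45. The other probe set of Cebpd had the opposite sign. The adipocyte list passed, as lower, without wild-type replicate 2 (adjusted p = 3.54e-06). Fatty acid and sterol synthesis had 15 of 22 higher means (camera adjusted p = 0.148), with Elovl5, a fatty acid elongase gene, at 0.19 log2, and passed without Rarb-null replicate 2 (0.0044) or wild-type replicate 1 (4.43e-06). Respiratory chain genes had 17 of 23 higher means (camera adjusted p = 0.0510), led by Sdha at 0.32 log2 and Atp5b at 0.31 log2, and passed without Rarb-null replicate 2 (1.54e-06) or wild-type replicate 1 (0.000697). The respiratory chain list also passed after a further quantile normalization (0.0423) or median centring (0.0451). Brown and beige adipocyte genes had 13 of 17 higher means (camera adjusted p = 0.132), but Rarb-null replicate 3 alone lay far above the rest, and the list passed without Rarb-null replicate 2 (1.73e-05). The mean of that list on this array was 1.71 log2 above the mean of the 6 arrays, and the other 5 arrays lay between -0.94 and 0.13. Elovl3, a fatty acid elongase gene of brown fat, read 7.88 ± 2.28 against 6.39 ± 0.32, and Slc27a2, a fatty acid transporter gene, differed by 1.15 log2. All passes in this paragraph used the preset correlation of 0.01. The estimated correlation was 0.52 for the adipocyte list, 0.52 for fatty acid and sterol synthesis, 0.81 for the respiratory chain and 0.58 for brown and beige adipocytes. With it, camera on all arrays gave an unadjusted p of 0.553, 0.565, 0.540 and 0.521.

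Cell cycle and mammary epithelial genes had higher means on Rarb-null arrays, and the arrays of each genotype were split. All 22 measured cell cycle genes had a higher Rarb-null mean, with a median of 0.62 log2, and camera gave an adjusted p of 0.0322 with the preset correlation, against an unadjusted p of 0.477 with an estimated correlation, which was 0.99 in this list. Cell cycle list means relative to the 6 arrays were 1.28, 1.28 and -1.52 on Rarb-null replicates 1 to 3 and -1.11, 1.37 and -1.30 on wild-type replicates 1 to 3. High and low arrays thus occurred in both genotypes, and the exact permutation p of the list mean was 1. Ccna2, the cyclin A gene, read 8.91 ± 1.63 against 7.80 ± 1.69, and the replication gene Mcm3 differed by 0.63 log2. With 1 array left out, the mean difference of the list ran from 0.21 to 1.61 log2. The cell cycle call held without Rarb-null replicate 3 (adjusted p = 1.8e-13) or wild-type replicate 2 (1.96e-08) and was lost without Rarb-null replicate 1 or 2 or wild-type replicate 1 or 3, with an adjusted p of 0.662 at most, without wild-type replicate 3. Of 22 mammary epithelial markers, 17 had a higher mean, with a median of 0.40 log2 (camera adjusted p = 0.035; p = 0.376 with an estimated correlation). Their list mean was 0.20, 0.24 and 0.18 on the Rarb-null arrays and -0.15, 0.46 and -0.92 on the wild-type arrays. The list includes milk protein genes. The mean of the 18 other markers was 0.25, 0.35 and -0.22 on the Rarb-null arrays and -0.28, 0.55 and -0.64 on the wild-type arrays. Rarb-null replicate 3 thus lay above the mean of the 6 arrays only with the milk protein genes included. Cldn4 and Cldn7, both claudin genes of epithelial junctions, went opposite ways, at 7.71 ± 0.44 against 8.40 ± 0.42 and 10.93 ± 0.48 against 10.31 ± 0.72. With 1 array left out, their mean difference ran from 0.05 log2, without wild-type replicate 3, to 0.74 log2, without wild-type replicate 2. The epithelial call held without the same arrays, Rarb-null replicate 3 (0.00805) or wild-type replicate 2 (5.99e-07), and was lost without any other array, with an adjusted p of 0.805 without wild-type replicate 3.

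**Figure D3:**
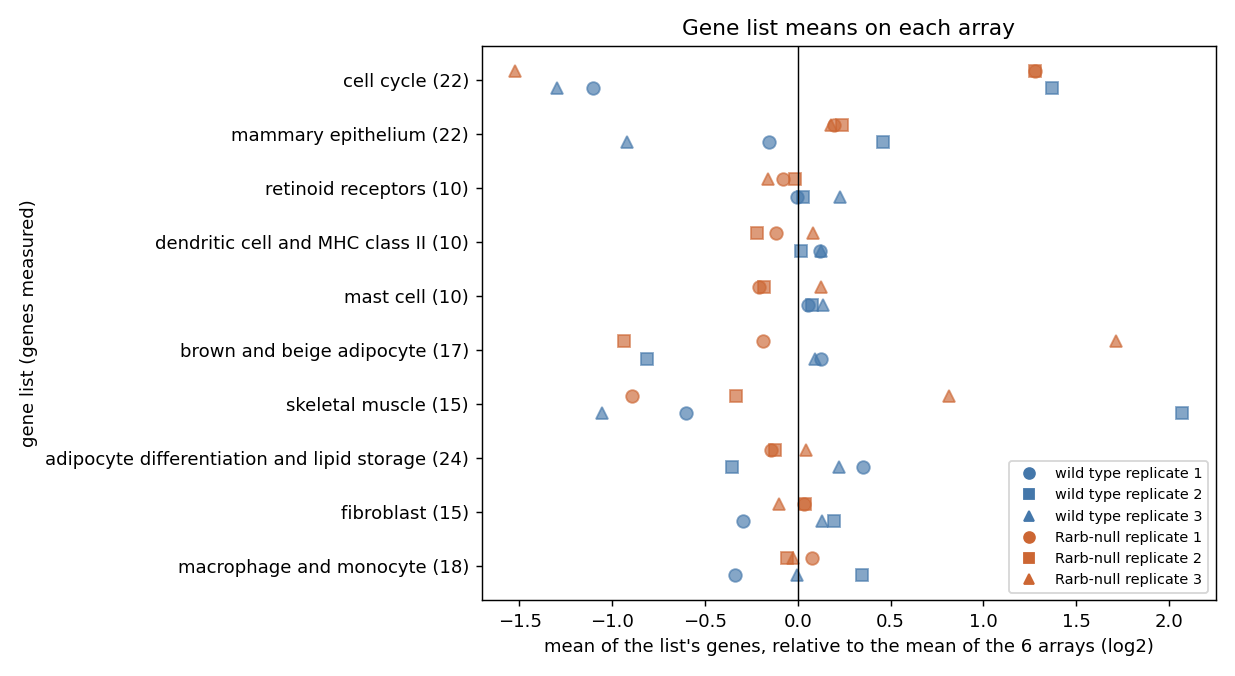
Mean of each gene list (y axis, with the number of genes measured) on each array relative to the mean of the 6 arrays (x axis, log2); colours mark genotype and symbols the replicate. In the cell cycle list 2 Rarb-null arrays and 1 wild-type array lie between 1.28 and 1.37, and the other 3 arrays lie between -1.52 and -1.11.

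Markers of mast cells and of antigen-presenting cells had lower means on Rarb-null arrays. Of 10 mast cell markers, 8 had a lower mean, with a median of -0.16 log2 (camera adjusted p = 0.035; p = 0.202 with an estimated correlation). Mast cell was the 1 list with members past 0.05 adjusted over the list alone: these were Ms4a2, given above, and Mcpt4, a mast cell protease gene, at 7.31 ± 0.20 against 7.86 ± 0.15, with 0.0169 as the smallest adjusted p in the list. Adjusted over all probe sets, 0 passed. Of 10 dendritic cell and MHC class II genes, 9 had a lower mean, with a median of -0.15 log2 (camera adjusted p = 0.035; p = 0.217 with an estimated correlation). Cd74, the class II invariant chain gene, read 9.77 ± 0.12 against 10.13 ± 0.08, and H2-Eb1 8.22 ± 0.21 against 8.61 ± 0.26. The mast cell list mean was -0.21, -0.18 and 0.12 on the Rarb-null arrays and 0.06, 0.08 and 0.13 on the wild-type arrays, an overlap with an exact permutation p of 0.3, and the dendritic cell list mean was -0.12, -0.22 and 0.08 against 0.12, 0.02 and 0.12, with an exact permutation p of 0.2. The mast cell call held without Rarb-null replicate 3 (adjusted p = 0.000862) or wild-type replicate 1 (0.0337) and was lost without any other array, with an adjusted p of 0.194 at most, without Rarb-null replicate 1. The dendritic cell call held with 1 array left out only without Rarb-null replicate 3 (0.00192), the array with the highest Rarb-null list mean, and was lost without any of the other 5, with an adjusted p of 0.182 at most, without Rarb-null replicate 2.

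The other marker lists did not pass, and members named by the fixed rule are given as differences in log2. Camera adjusted p was 0.968 for fibroblasts (Cd34 0.55, S100a4 -0.36), 0.132 for vascular smooth muscle and pericytes (Lmod1 -0.39, Tagln -0.29), 0.968 for vascular endothelium (Erg -0.67, Tek 0.34), 0.285 for lymphatic endothelium (Lyve1 0.29, Reln 0.47). It was 0.766 for macrophages and monocytes (Aif1 -0.55, C1qb -0.55), 0.968 for T and NK lymphocytes (Tcf7 0.32, Gzma -0.21), 0.788 for B lymphocytes and plasma cells (Jchain 0.81, Ighm -0.97) and 0.892 for neutrophils and eosinophils (S100a9 -0.42, S100a8 -0.40). It was 0.635 for skeletal muscle (Casq1 -0.33, Eno3 -0.39), 0.180 for Schwann cells and nerve (Pmp2 -0.36, Mbp -0.48), 0.292 for skin and hair (Krt10 -0.44, Dsg1a 0.20), 0.180 for erythrocytes (Hbb-b1 -0.95) and 0.788 for salivary gland (Aqp5 0.52, Bpifa2 0.16). Lyve1, Reln and Eno3 each had 1 other probe set, of the opposite sign, and of the 3 other probe sets of C1qb, 1 had the same sign. Without wild-type replicate 2 these passed: vascular smooth muscle (0.0337), vascular endothelium (0.0312) and erythrocyte genes (0.0271) as lower, macrophage (0.00626) and skeletal muscle genes (0.00626) as higher. Skeletal muscle genes passed as lower without wild-type replicate 3 (0.0205), so their call turned with the array left out. Schwann cell and nerve genes passed as lower with the mean of all probe sets of a gene (0.0496).

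In all, 5 of the 36 lists passed camera with the preset correlation: retinoid receptors, cell cycle, mammary epithelium, dendritic cell and MHC class II, and mast cell. With an estimated correlation 0 passed, with a smallest adjusted p of 0.985, and with fry 0 passed, with a smallest adjusted p of 0.949. The count was 0 without the dimmest 40% of probe sets, 1 without Rarb-null replicate 1, 9 without wild-type replicate 2 and 1 without wild-type replicate 3. With the first principal component or the hybridisation controls as covariate, both added later, retinoid receptors kept the call (adjusted p = 0.0287 and 0.00828), and the other 4 lists lost it with either. The cell cycle mean difference went from 0.69 log2 to -0.09 and -0.0030, but those of the other lists kept their sign, and with the hybridisation controls most of their size: mammary epithelium from 0.41 to 0.25 and 0.39, dendritic cell from -0.17 to -0.12 and -0.13, and mast cell from -0.18 to -0.13 and -0.16. The same covariates called respiratory chain genes (1.27e-06 and 1.07e-06), fatty acid and sterol synthesis (0.00501 and 1.02e-06) and brown and beige adipocyte genes (1.08e-06 and 0.0065) as higher, and basement membrane (0.047 and 0.0233) and interferon response genes (0.000658 and 0.0167) as lower. The hybridisation controls alone also called circadian clock genes as higher (0.000807). All list calls with a covariate added or an array left out used the preset correlation of 0.01. For the lists that only the covariates called here, the estimated correlation ran from 0.21 (circadian clock) to 0.81 (respiratory chain). With it, and without covariates, camera gave them an unadjusted p of 0.302 to 0.565. The difference between the 3' and 5' control probe sets of Actb, which grows as RNA degrades, was lower on Rarb-null arrays (1.30, 1.13 and 1.15 log2) than on wild-type arrays (1.33, 1.49 and 1.71 log2) without overlap. The same difference for Gapdh overlapped, at 2.71, 2.84 and 2.28 against 2.37, 3.16 and 3.27 log2. A part of RNA quality in the list differences was therefore not excluded.

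Genes beside Rarb on its chromosome were compared with the rest because DNA around a targeted gene can come from another strain. Within 10 Mb of Rarb, 2 of 98 genes (2.04%) had an unadjusted p under 0.01, against 154 of 17567 elsewhere (0.877%). The odds ratio was 2.36 and Fisher's exact p, two-sided, was 0.215. It was 4.05 within 5 Mb (Fisher's exact p = 0.0930) and 2.55 within 20 Mb (exact p = 0.0792), and a further quantile normalization gave 4.43 within 10 Mb (exact p = 0.0151), so the outcome of this test depended on the scaling. No gene in the window passed the threshold over all probe sets. Rtraf had the smallest p in the window, and Mapk8, given above, had the smallest within 20 Mb. Without wild-type replicate 3 no gene near Rarb had a p under 0.01. The list of genes next to Rarb, with 8 measured, gave a camera adjusted p of 0.985, with Ngly1 at 11.47 ± 0.14 against 11.19 ± 0.13 and Oxsm at -0.68 log2.

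Arrays did not group by genotype. Correlations over all probe sets were highest among Rarb-null replicates 1 and 2 and wild-type replicate 2, from 0.9934 to 0.9956, and every other pair lay at or below 0.9885. The mean correlation within genotypes minus that between them was -0.000204, and an exact permutation test, one-sided over 10 splits, gave p = 0.3. The first principal component held 45.9% of the variance. Among the 500 genes with the largest loadings on it were all 22 measured cell cycle genes and 11 of 17 brown and beige adipocyte genes, where 0.536 and 0.414 are expected by chance. They also held 6 of 22 mammary epithelial markers (Fisher's exact test, adjusted p = 0.000131) and 3 of 15 skeletal muscle genes (adjusted p = 0.0473).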

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

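The first principal component and the hybridisation controls were added as covariates after the absence of calls had been seen; the other alternatives were chosen before. The count of probe sets past 0.05 was 0 in every setting except without Rarb-null replicate 2 (range 0 to 1 over arrays left out), with 2351 probe sets at an unadjusted p under 0.05 in the comparison as reported. That latter count was 1566 without the dimmest 40% of probe sets, where fewer were tested, and ran from 1147 to 4418 with 1 array left out. Rarb stayed above 0 in all refits, and in 1412 refits of the 90 named genes 0 passed and 4 turned sign. Lists past the threshold numbered 5, against 0 without the dimmest 40%, 0 without probe sets of mean under 6, 0 with camera and an estimated correlation, 0 with fry, 8 with the mean of all probe sets of a gene, and 1 to 9 with 1 array left out. The correlations of same-numbered Rarb-null and wild-type arrays, as deviations from their group means, were -0.20, 0.45 and 0.29, so the numbers were not taken to pair mice; with the replicate block 0 probe sets passed, and of the lists 3 did (cell cycle, mammary epithelium and mast cell), while retinoid receptors and dendritic cell genes lost the call, and not every array correlated best with its own number. Further quantile normalization gave an odds ratio of 4.43 for genes near Rarb (Fisher's exact p = 0.0151), and arrays left out gave 0 to 4.41, with 0 without wild-type replicate 3. For arrays apart from the rest, the within-genotype minus between-genotype correlation ran from -0.00185 to 0.00312 with 1 array left out. For these changes the cause was not tested beyond the smaller number of arrays or probe sets. The planned use of per-sample values from the other deposited table was not run, since it holds group means and comparisons only. Signal over background limits the dim probe sets, and no detection flags were given.

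The mean differences of these lists turned sign, as log2 values, over the 6 fits with 1 array left out: fibrillar matrix -0.12 to 0.15, TGF-beta and BMP -0.082 to 0.044, Wnt -0.10 to 0.054, growth factors -0.051 to 0.0033, hormone receptors -0.018 to 0.12, fatty acid and sterol synthesis -0.086 to 0.36, brown and beige adipocyte -0.39 to 0.96, respiratory chain -0.055 to 0.26, interferon response -0.30 to 0.057, immediate early genes -0.11 to 0.013 and circadian clock -0.0067 to 0.21. The same held for fibroblast at -0.17 to 0.075, vascular endothelium -0.20 to 0.073, macrophage -0.17 to 0.17, T and NK lymphocyte -0.13 to 0.043, B lymphocyte -0.15 to 0.031, neutrophil -0.25 to 0.11, skeletal muscle -0.87 to 0.69 and salivary gland -0.020 to 0.13, and for the genes Slc27a2 (-0.025 to 2.03), Casq1 (-0.70 to 0.12) and Eno3 (-0.76 to 0.22). With the first principal component as covariate, means turned to -0.048 for fibrillar matrix, 0.025 for TGF-beta and BMP, -0.094 for cell cycle, 0.018 for vascular endothelium, 0.072 for T and NK lymphocyte, 0.018 for B lymphocyte and 0.12 for neutrophil. With the hybridisation controls as covariate they turned to -0.13 for fibrillar matrix, 0.057 for TGF-beta and BMP, -0.011 for hormone receptors, 0.00141 for list: adipocyte differentiation and lipid storage, -0.0030 for cell cycle, 0.0052 for list: vascular endothelium, 0.077 for T and NK lymphocyte, 0.0032 for list: B lymphocyte and plasma cell and 0.097 for neutrophil, and Reln to -0.010. The macrophage mean turned to 0.017 with the mean of all probe sets of a gene, and the neutrophil mean to 0.24 without the dimmest 40%. Macrophage and skeletal muscle genes passed upward without wild-type replicate 2; the other turned lists stayed past neither side in the turned setting. The cause was not tested.

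Splits of the 6 arrays into 3 and 3 number 10 with the labelled one included, too few for a share under 0.05. As labelled, the split gave 0 probe sets, which all 10 splits reach, and the highest other count was 1055. It gave 5 lists, which 9 of the 10 splits reach, and the highest other was 15. The split with 1055 probe sets sets Rarb-null replicates 1 and 2 and wild-type replicate 2 against the rest, which points to a structure of the arrays that crosses the genotype labels.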

Other observations

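The genes of these paragraphs were chosen after their values were seen, as were all tests except the one of array signal and the one of exchanged labels. Those 2 were set before their own outcomes were seen. Both concern the split of the arrays by cell cycle genes, however, so they were chosen after that split was seen. Epithelial genes were bright on all 6 arrays, although the tissue is labelled a cleared fat pad. Epcam read 12.71 to 13.61, Krt8 11.64 to 12.76 and the luminal transcription factor gene Elf5 8.99 to 12.10. The milk protein gene Csn2 read 13.90 to 14.65 on 5 arrays and 7.63 on wild-type replicate 3. Lalba, another milk protein gene, read 13.10 on Rarb-null replicate 3, 10.02 on wild-type replicate 1 and at most 8.12 on the other arrays. Ucp1, the uncoupling protein gene of brown fat, spanned 6.11 to 13.28 with its highest value on Rarb-null replicate 3. The muscle gene Myh4 spanned 5.12 to 12.35 with its highest value on wild-type replicate 2. Erbb2, named in a description attached to every sample, read between 7.50 and 7.63 on all arrays. Xist, transcribed from the inactive X chromosome, read 12.54 to 13.24, and the Y-linked genes Ddx3y and Kdm5d between 3.87 and 5.03.

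Cell cycle genes separated the arrays across genotypes, with Top2a at 10.28 to 10.40 on Rarb-null replicates 1 and 2 and wild-type replicate 2 and at 5.98 to 7.13 on the others. The list's range of 2.9 log2 lay at percentile 100 of 10000 lists matched on mean signal, whose highest range was 0.68. The split was thus not a shift shared by genes of like signal, which RMA would largely remove. A difference in hybridisation or labelling cannot be argued against in this way. Any genes that vary together exceed random lists whatever the cause, as skeletal muscle genes did at 3.13 log2. The hybridisation controls parted the arrays the same way, though not in the same order within each side. They read 10.64 to 10.71 on the 3 arrays high in cell cycle genes. On wild-type replicate 3, Rarb-null replicate 3 and wild-type replicate 1 they read 10.80, 10.98 and 11.58. With them as covariate the genotype difference of the list went from 0.69 to -0.0030 log2. With the first principal component, which parts the arrays the same way, it went to -0.09. Any covariate with this split would take up much of that difference, so the drop cannot show a link to the controls. Such a link stays open. A different share of epithelium alone was argued against, since 16 epithelial markers in the same signal range spanned 1.22 log2. These markers were higher on the same arrays, however. Of 22 epithelial markers, 6 were among the 500 genes that weigh most on the first principal component, so epithelium may account for part. An exchange of labels between Rarb-null replicate 3 and wild-type replicate 2 cannot be told apart from a true split. With these exchanged, genes near Rarb had an odds ratio of 0.556 at an unadjusted p under 0.01, against 2.36 as labelled (highest of the other splits 4.1). The counts were 5 of 98 against 1550 of 17567 elsewhere when exchanged, and 2 of 98 against 154 of 17567 as labelled. Fisher's exact p was 0.280 and 0.215. The exchanged split is the one that calls most genes elsewhere, which lowers its odds ratio, so these ratios decide nothing about the labels. As given above, the labelled value was higher still after a further quantile normalization. Rarb would read 6.50, 6.61 and 6.01 against 6.95, 7.41 and 6.65 without overlap. Any 6 different values part in this way in 1 of the 10 splits. The nearest values of the 2 sides were 6.61 and 6.65, so this decides nothing about the labels. The strains around Rarb and the place of its probe set are unknown, and the growth stage of the gland was not tested.

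A candidate explanation for milk protein and epithelial signal is epithelium left in the tissue taken. The array lowest in caseins, wild-type replicate 3, was also lowest in the 18 epithelial markers other than milk proteins, at -0.64 log2 relative to the 6 arrays. Those markers spanned 1.19 log2 and caseins 5.66 log2, which argues against a share of epithelium alone as the source of the casein differences between arrays. The casein range rests on wild-type replicate 3 at -4, however. On the other arrays caseins ran from 0.15 to 1.66 and the markers from -0.28 to 0.55, and there the ranges do not decide. Rarb-null replicate 3, highest in caseins (1.66), lay at -0.22 in the markers. Among further epithelial markers, Krt14 read 9.61 to 10.63 and Trp63 8.93 to 11.28 over the 6 arrays. Epithelium in all samples as the source of the signal itself was thus not argued against and stays open. Cross-hybridisation of single probe sets was argued against, since all 7 casein probe sets with a mean above 6 were lowest on wild-type replicate 3. When the fat pads were cleared is not stated in the labels, and no biological explanation by genotype was tested.

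A pair of probe sets that share symbols in the authors' deposited table, 1 of which also lists the immunoglobulin lambda gene Igl-V1, were higher on every Rarb-null array, by 2.34 and 1.99 log2. More plasma cells in Rarb-null tissue stays open, since J chain and abundant kappa and heavy chain probe sets differed by a median of 0.40 log2 but went both ways. J chain differed by 0.81, the 3 Igh-VJ558 probe sets by 0.63 to 0.93, and Ighg1 by 0.43 and 0.39. The kappa probe sets differed by 0.40, 0.23 and 0.13, and Ighm by -0.59 and -0.97. Selection of large values among all probe sets stays open, with an adjusted p in limma of 0.908 over 45037. The probe set of the pair with 2 provisional symbols was the 1 that passed without Rarb-null replicate 2 (2.92 log2, adjusted p in limma 0.0339). That array held its lowest Rarb-null value, 7.70 against 9.36 and 9.49. Leaving it out therefore widens the difference, and the pass gives no separate evidence. A difference between littermates in the lambda locus was not tested.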
